A study of Bacillus subtilis with 6 samples.

How the data were processed

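Ribosome footprints were sequenced from Bacillus subtilis cultures of 2 strains. The strain labelled WT is a production strain that lacks the sporulation sigma factor gene sigF and 7 genes for secreted proteases, and it carries a high-copy plasmid, kept by kanamycin, with an α-amylase gene of Geobacillus stearothermophilus under the aprE promoter. The ppGpp0 strain is the same strain without rel, sasA and sasB, the 3 genes for synthetases of the alarmone (p)ppGpp. Per the labels' protocols, cultures of both strains grew at 30 °C in a rich medium, were harvested into crushed frozen buffer with 1 mM chloramphenicol, and gave footprints by micrococcal nuclease digestion and a sucrose gradient of 10 to 50%. The 6 libraries fall into 3 groups of 2: WT at 8 h, ppGpp0 at 8 h and ppGpp0 at 16 h.

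The deposited values are raw counts of footprint reads per annotated gene, with 1 library per table. Per the submitters' processing notes, adapters were trimmed with cutadapt 4.0, read quality was checked with FastQC 0.73 and reads were aligned with Bowtie2 2.4.2. The counting program, the genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Near-identical rRNA and tRNA genes, overlapping genes and antisense pairs are therefore uncertain. The tables give locus tags without coordinates. Names and gene classes came from the RefSeq annotation of assembly ASM904v1, which was used for nothing else: 4416 of 4422 locus tags matched and 6 did not, among them BSU41070, whose gene is not named here. The matched tags were 4161 protein-coding genes, 78 pseudogenes, 30 rRNA genes, 86 tRNA genes and 61 other RNA genes.

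Library totals ran from 1428810 to 2428512 counts, of which 89.0 to 93.4% fell on protein-coding genes. In a library, 2492 to 2972 protein-coding genes had at least 10 counts, and the median protein-coding gene had 21 to 53 counts. The cultures behind the replicates are not described as independent in the labels, so the p-values measure the spread between these libraries only. Intervals and floors cover counting error only.

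Genes were tested in R 4.3.3 with edgeR 4.0.16: protein-coding genes alone, filterByExpr with a minimum count of 10 and a minimum total of 15, TMM normalization, and a robust quasi-likelihood test in 1 fit of all 6 libraries with group as the sole factor and 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. Log2 fold changes are given ± SE. TMM-scaled CPM values are given as mean ± SD of 2 libraries. A gene with 0 counts in a group got a lower bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with its 95% counting interval.

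Gene lists, 48 in number with 972 members, of which 922 matched a locus tag, were written from general knowledge of B. subtilis. Of these, 45 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison; the deleted genes stayed out of them. Camera with an estimated correlation and fry were run beside it. The share of a library's protein-coding counts that fell on a list is given as mean ± SD. An exact two-sided permutation test of 2 libraries against 2 cannot go below 0.333, so shares are described without a call. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

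The groups, the lists, the tests of genes and lists in both comparisons, the named-gene rule and all but 2 alternatives were fixed before the data were examined. The tests of the covariance between the comparisons were chosen after the fold changes were seen. For each comparison the rule named the deleted genes, the 6 genes with the largest rise and the 6 with the largest fall, and up to 4 members of each list with the largest change. All of these had to pass the threshold, reach 10 CPM in the higher group and have both libraries of one group above both of the other. A list with fewer than 2 such members gave its 2 most abundant members instead. The alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a mean of at least 50 counts, non-coding genes kept, only the 4 libraries of a comparison, the replicate number as a block, the 20 most abundant genes left out, and each library left out in turn. Keeping the unmatched row BSU41070 and thinning all libraries to one depth were added after seeing the data.

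The steps were tested on simulated data drawn from the means and sizes of these libraries, with 50 of 2920 genes changed at each size. For ppGpp0 against WT, 12% of genes changed 1.5-fold, 58% at 2-fold, 94% at 4-fold and 98% at 8-fold were recovered, and 8 of 139 calls were false. For 16 h against 8 h these shares were 12%, 62%, 98% and 98%, and 9 of 144 calls were false.

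Footprint counts per gene cannot show where on a gene ribosomes paused. No RNA-seq library was used here, so changes in mRNA level and in translation per mRNA were not separated. WT at 16 h was not analysed here, so no genotype-by-time test was made. The batch label holds the time point, so time and that label cannot be told apart. Non-coding genes, pseudogenes and unmatched tags were left out of the main tests because the counting of repeated and structured RNAs is not described.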

Results

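Ribosome footprints were counted in 6 libraries of B. subtilis: WT at 8 h, the (p)ppGpp-free strain ppGpp0 at 8 h and ppGpp0 at 16 h, with 2 replicates each. (p)ppGpp is the alarmone that bacteria make when amino acids run short, and ppGpp0 lacks the 3 genes that make it. Total counts were 2428512 and 1575225 for WT at 8 h, 2082522 and 1428810 for ppGpp0 at 8 h, and 1653099 and 2071103 for ppGpp0 at 16 h. Replicates correlated across protein-coding genes on the log2 scale with r = 0.986 for WT, 0.971 for ppGpp0 at 8 h and 0.986 for ppGpp0 at 16 h, where genes are not independent replicates. On the first principal component (61.4% of the variance) the WT libraries lay at -31.97 and -31.19, ppGpp0 at 8 h at 37.93 and 44.57, and ppGpp0 at 16 h between them at -9.81 and -9.53. The second component (30.9%) set the 16 h libraries apart from both 8 h groups.

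**Figure D1:**
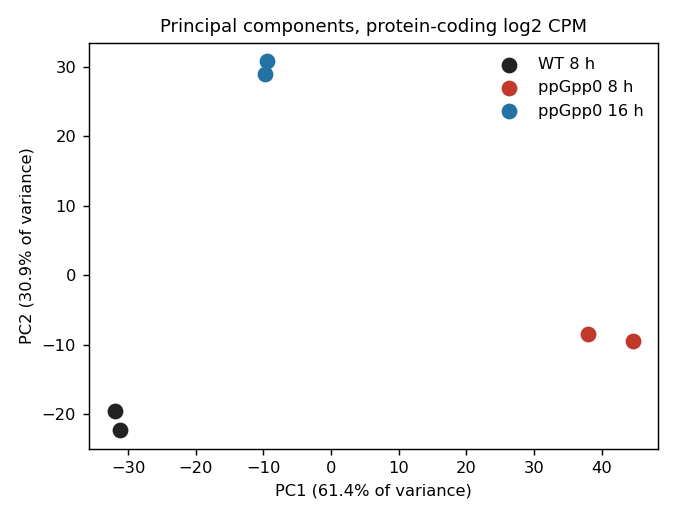
Principal components of protein-coding log2 CPM; each point is 1 of the 6 libraries and the axes give the share of variance (61.4% and 30.9%). Replicates lie together, and ppGpp0 at 16 h lies between the other groups on the first axis.

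The deleted genes were read first, since they check the labels. The synthetase gene rsh (rel, BSU27600) had 248 ± 5.66 CPM in WT (mean ± SD, n = 2) and 14.7 ± 3.61 in ppGpp0 at 8 h, a log2 fold change of -4.10 ± 0.28 (SE; edgeR adjusted p = 2.83e-08), and 3.92 ± 0.918 at 16 h. Of the 2 small synthetase genes, relQ (BSU38480) fell from 85.8 ± 4.65 to 1.56 ± 1.05 CPM (-5.61 ± 0.42, edgeR adjusted p = 6.33e-08). Its partner relP (BSU11600) fell from 76.6 ± 1.68 CPM to 0 counts, at least 75.8-fold lower (edgeR adjusted p = 6.26e-08). At 16 h relQ had 9.98 ± 2.53 CPM and relP 1 count per library. Among genes deleted in both strains, sigF and vpr had 0 counts in all 6 libraries, and nprE, mpr, nprB and bpr had at most 13 counts in any library. Some counts fell on aprE, whose promoter the plasmid carries: 30.6 ± 6.14 CPM in WT, 7.92 ± 3.86 in ppGpp0 at 8 h and 24.0 ± 3.89 at 16 h. Counts on epr gave 12.4 ± 0.532, 1.81 ± 0.923 and 1.2 ± 0.152 CPM in the same order.

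The comparison of ppGpp0 with WT at 8 h asks how footprints differ in a production strain that lacks the alarmone. The 2 strains may have reached different growth stages by 8 h, which was not tested and cannot be told apart from genotype. In ppGpp0, footprints shifted toward making ribosomes and nucleotides. They shifted away from the synthesis of branched-chain amino acids, tryptophan and arginine, and from other genes that the GTP-sensing repressor CodY controls. Genes of competence and antibiotic synthesis also lost footprints. Chaperones and envelope-stress genes carried more footprints. Of 2920 genes tested, 1583 (54.2%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 789 higher and 794 lower in ppGpp0, and 531 and 622 of these changed at least 2-fold. In 2249 genes (77.0%) both libraries of one strain lay above both of the other, where chance gives 33.3%. Camera called 23 of 45 lists, 11 up and 12 down. With an estimated correlation it called 0 lists in this comparison and 0 in the other, with a lowest adjusted p of 0.0797 and 0.121 and 8 lists below 0.05 unadjusted in each. Fry called 31 and 32. A simulated 2-fold shift of 1 list passed the estimated-correlation test (camera adjusted p = 0.00447). Genes were drawn independently there and no other gene changed, so it does not show what that test could detect in these data.

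Ribosomal protein genes took 15.7 ± 0.417% of coding footprints in ppGpp0 and 8.46 ± 0.425% in WT, a ratio of 1.86. Of 52 members, 47 rose and 1 fell, or 47 and 2 adjusted over the list alone, with a median log2 fold change of 1.23. The camera adjusted p = 1.73e-10, and adjusted p = 0.206 with an estimated correlation. Examples were rplA (2.19 ± 0.19), rpmGA (1.93 ± 0.21), rpsQ (1.87 ± 0.25) and rpsD (1.84 ± 0.20). Translation factors went the same way, with 12 of 14 higher (13 adjusted over the list alone; camera adjusted p = 0.0150, adjusted p = 0.237 with an estimated correlation), but without ppGpp0 8 h replicate 1 the camera adjusted p was 0.0515. Their share was 1.28 times that of WT, and 1.5 times with the 20 most abundant genes left out, which removes tufA and fusA from the list. The gene hpf for the factor that pairs idle ribosomes was lower (-0.73 ± 0.18, edgeR adjusted p = 0.00384).

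Nucleotide genes rose strongly. The largest rises among genes that met the naming rule were the GMP reductase gene guaC, from 22.1 ± 6.79 to 2839 ± 775 CPM (7.04 ± 0.30, edgeR adjusted p = 3.81e-10), and the purine permease gene pbuO, from 5.25 ± 1.09 to 390.5 ± 71.4 CPM (6.16 ± 0.31, edgeR adjusted p = 1.03e-09). In purine synthesis 14 of 15 genes rose (14 adjusted over the list alone), among them purA (4.02 ± 0.19), purS (3.13 ± 0.27), purB (3.02 ± 0.21) and purE (2.85 ± 0.24); the share went from 0.792 ± 0.104% to 3.09 ± 0.315%. By camera, adjusted p = 2.10e-10, and adjusted p = 0.219 with an estimated correlation. Purine salvage and uptake had 8 of 11 higher and 1 lower, the same counts adjusted over the list alone, pbuG among the higher (3.15 ± 0.25; camera adjusted p = 1.22e-05, adjusted p = 0.206 with an estimated correlation). All 12 tested pyrimidine synthesis genes rose, also adjusted over the list alone, with a median of 3.54. These included pyrB (5.12 ± 0.34), pyrAA (4.68 ± 0.39), pyrC (4.10 ± 0.67) and the uracil permease gene pyrP (3.79 ± 0.32). The camera adjusted p = 2.15e-11, and adjusted p = 0.237 with an estimated correlation. Members of a list are not independent: the estimated correlation was 0.193 for purine and 0.441 for pyrimidine synthesis, above the preset 0.01.

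**Figure D2:**
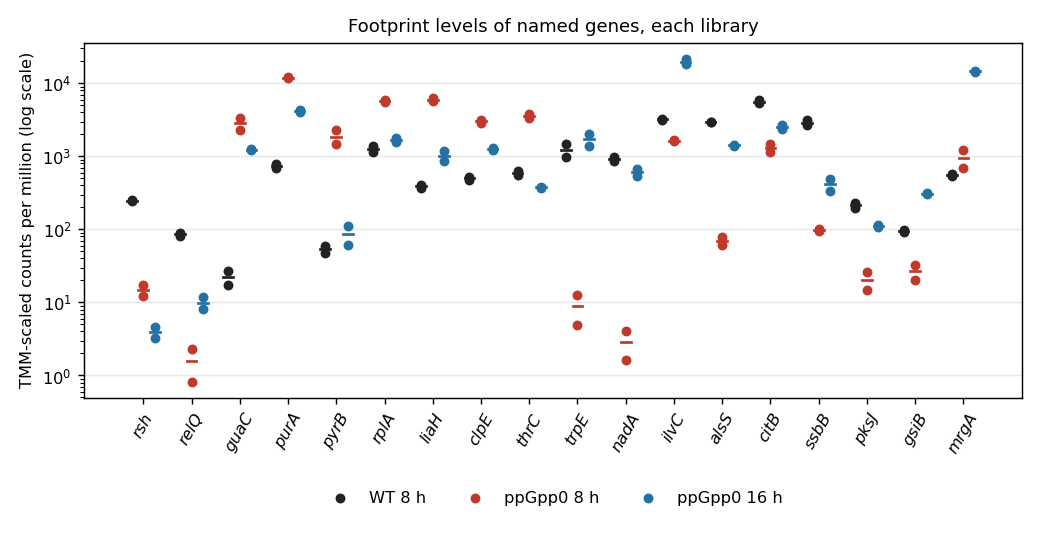
TMM-scaled CPM (log axis) of 18 named genes; points are single libraries and bars the mean of 2. The nucleotide genes guaC, purA and pyrB were highest in ppGpp0 at 8 h, and trpE, nadA, alsS and ssbB were lowest there.

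Amino acid synthesis changed by pathway: 2 of its 4 lists fell and 2 did not pass. The biosynthesis genes of histidine, tryptophan and arginine had 14 of 22 lower and 4 higher (the median was -3.81): trp and arg genes fell, trpE (-7.04 ± 0.40) and trpB (-6.80 ± 0.37) among them, while the 4 that rose were his genes. trpD dropped to 1 count, a ratio of 552 with an interval of 98.7 to 21814. The camera adjusted p = 2.44e-05, and adjusted p = 0.440 with an estimated correlation; the counts adjusted over the list alone were 14 lower and 4 higher. Other CodY targets had 27 of 28 lower, 27 also adjusted over the list alone, with a median of -2.56 and a share of 0.274 ± 0.0266% against 1.96 ± 0.0837%. The amino-sugar genes frlD (-6.39 ± 0.48) and frlO (-6.16 ± 0.41) were among them; the camera adjusted p = 1.42e-19, and adjusted p = 0.0797 with an estimated correlation. Branched-chain amino acid synthesis had 10 of 11 lower, 10 adjusted over the list alone, with ilvD at -1.54 ± 0.22, leuA at -1.19 ± 0.20 and ilvC at -0.96 ± 0.17. Its camera adjusted p = 0.0283, adjusted p = 0.237 with an estimated correlation, and the camera adjusted p was 0.0546 without ppGpp0 8 h replicate 1. Threonine, lysine, serine and aromatic synthesis had 8 of 21 lower and 4 higher (camera adjusted p = 0.95), with thrC (2.58 ± 0.19) and hom (1.84 ± 0.18) among the higher. Methionine and cysteine synthesis had 5 of 16 lower and 4 higher (camera adjusted p = 0.967).

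TCA cycle genes lost footprints, and so did single genes of NAD and acetoin synthesis. Among genes with more than 3 counts in each group that met the naming rule, the largest falls were in NAD synthesis, nadA from 923 ± 89.4 to 2.84 ± 1.69 CPM (-8.22 ± 0.35, edgeR adjusted p = 3.69e-10) and nadC from 1206 ± 44.0 to 6.33 ± 0.836 CPM (-7.54 ± 0.29, edgeR adjusted p = 2.42e-10), while yhfW went to 0 counts, at least 27.9-fold lower. Of 15 TCA cycle genes 12 fell and 2 rose (13 and 2 adjusted over the list alone), and the share went from 3.93 ± 0.162% to 1.46 ± 0.184%. Aconitase (citB, -2.10 ± 0.20) and succinyl-CoA synthetase (sucC, -1.62 ± 0.24) fell, and the gluconeogenic gapB rose (1.90 ± 0.38); the camera adjusted p = 0.0150, and adjusted p = 0.488 with an estimated correlation. The acetoin genes alsS, from 2947 ± 45.0 to 70.3 ± 13.0 CPM (-5.40 ± 0.23), and alsD (-4.67 ± 0.24) fell, and the acetate kinase gene ackA rose (1.96 ± 0.19). Their list, overflow metabolism, had 5 of 10 lower and 3 higher, the same counts adjusted over the list alone (camera adjusted p = 0.0407, adjusted p = 0.243 with an estimated correlation). Its camera adjusted p was 0.0606 without ppGpp0 8 h replicate 1, 0.0583 without ppGpp0 8 h replicate 2, 0.0619 without ppGpp0 16 h replicate 1 and 0.0625 without ppGpp0 16 h replicate 2. The acetoin and acetate use list had 1 of 4 lower and did not pass (camera adjusted p = 0.609). Glycolysis had 7 of 16 higher and 2 lower (camera adjusted p = 0.133), and respiration and ATP synthase had 7 of 23 higher and 7 lower (0.882); neither list passed.

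**Figure D3:**
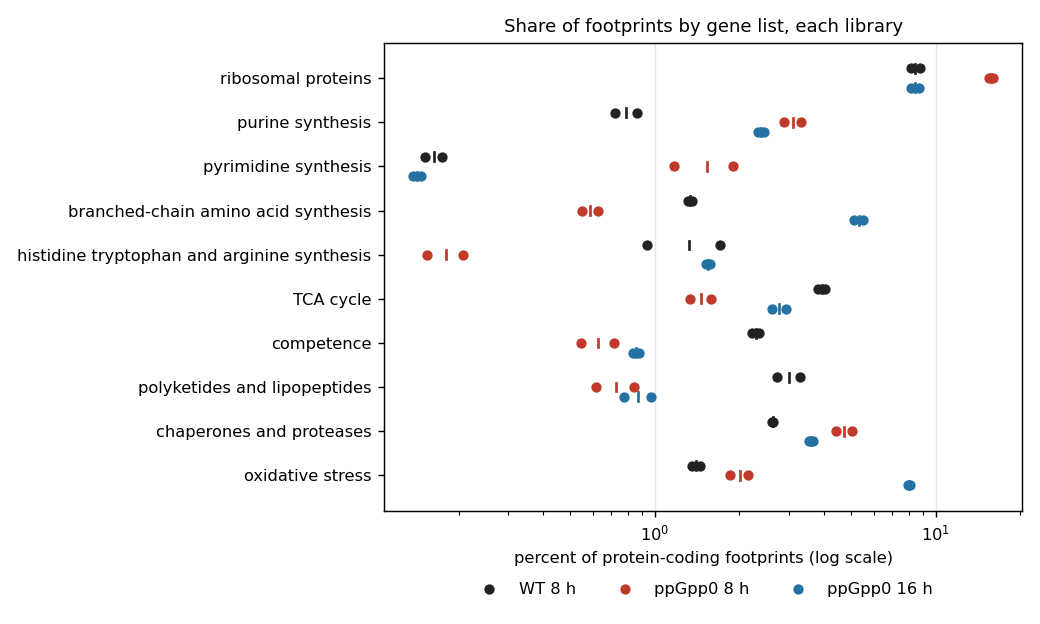
Percent of protein-coding footprints (log axis) on 10 gene lists; points are single libraries and bars the mean of 2. Ribosomal proteins took 15.7% in ppGpp0 at 8 h and 8.46% in WT.

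Competence and antibiotic synthesis fell. Of 23 competence genes 22 fell (23 adjusted over the list alone) with a median of -3.91, among them coiA (-6.91 ± 0.34), ssbB (-4.88 ± 0.25) and comFA (-4.66 ± 0.26). By camera, adjusted p = 9.32e-25, and adjusted p = 0.206 with an estimated correlation. The share ratio was 0.275, and 0.0818 with the 20 most abundant genes left out, which removes recA from the list. Polyketide and lipopeptide genes had 22 of 24 lower (22 adjusted over the list alone), the bacillaene genes pksL (-3.57 ± 0.39) and pksJ (-3.35 ± 0.28) among them (camera adjusted p = 9.04e-09, adjusted p = 0.237 with an estimated correlation). Secreted peptide antibiotics and cannibalism had 19 of 24 lower (19 adjusted over the list alone), with the bacilysin genes bacA (-3.44 ± 0.26), bacF (-3.14 ± 0.26) and bacB (-2.87 ± 0.21). The camera adjusted p = 8.30e-07, and adjusted p = 0.219 with an estimated correlation.

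General stress genes of SigB fell while protein-quality and envelope-stress genes rose. Of 34 SigB genes 22 fell and 1 rose (22 and 2 adjusted over the list alone), gspA (-3.24 ± 0.27) among the fallen, with camera adjusted p = 0.00782 and adjusted p = 0.219 with an estimated correlation. Chaperones and proteases had 15 of 20 higher (15 adjusted over the list alone), with clpE (2.60 ± 0.19), hslO (2.34 ± 0.23), hrcA (2.04 ± 0.22) and dnaJ (1.97 ± 0.20). Their share was 4.72 ± 0.457% against 2.62 ± 0.0256%; the camera adjusted p = 2.50e-05, and adjusted p = 0.219 with an estimated correlation. In the secretion-stress list 7 of 11 rose and 1 fell (7 and 1 adjusted over the list alone), carried by the envelope-stress operon with liaG (4.09 ± 0.31), liaH (3.95 ± 0.22) and liaI (3.12 ± 0.25). By camera, adjusted p = 0.000108, and adjusted p = 0.237 with an estimated correlation. Genes of SigW and SigM had 16 of 21 higher and 2 lower (17 and 2 adjusted over the list alone), with yceC (2.10 ± 0.19) and yceD (1.76 ± 0.18). The camera adjusted p = 0.000261, and adjusted p = 0.237 with an estimated correlation. Among the lists that did not pass were tRNA synthetases with 5 higher and 4 lower (camera adjusted p = 0.957) and motility with 9 and 6 (0.578). The share of motility genes was still lower, at 1.87 ± 0.256% in ppGpp0 against 2.73 ± 0.0299% in WT.

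The comparison of ppGpp0 at 16 h with 8 h follows the strain without the alarmone over time. Many groups moved against their difference from WT at 8 h: ribosome and pyrimidine genes fell, and branched-chain, tryptophan and arginine synthesis, SigB and competence genes and most polyketide genes rose. Ribosomal protein genes ended at 8.42 ± 0.379% of coding footprints beside 8.46 ± 0.425% in WT at 8 h. Branched-chain synthesis (5.31 ± 0.269% beside 1.33 ± 0.0351%) and SigB genes (1.0 ± 0.0337% beside 0.620 ± 0.00310%) ended above WT. Competence (0.856 ± 0.0308% beside 2.29 ± 0.0941%) and polyketide genes (0.872 ± 0.133% beside 3.01 ± 0.391%) stayed below it; 16 h was not tested against WT. WT at 16 h was not analysed here, so a change specific to the mutant cannot be separated from time. Of 2920 genes, 1395 (47.8%) changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 714 higher and 681 lower at 16 h, and 516 and 436 changed at least 2-fold. Without ppGpp0 16 h replicate 2, 450 genes were lower. In 2131 genes (73.0%) the libraries of the groups did not overlap, where chance gives 33.3%. Camera called 18 of 45 lists, 8 up and 10 down.

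Branched-chain synthesis and the histidine, tryptophan and arginine list had the largest rises in median among the tested lists. Branched-chain synthesis went from 0.589 ± 0.0519% to 5.31 ± 0.269% of coding footprints, with 9 of 11 genes higher (11 adjusted over the list alone) and a median of 3.06. ilvC went from 1647 ± 15.4 to 19893 ± 2483 CPM (3.59 ± 0.19), and leuD (4.60 ± 0.21) and leuB (3.82 ± 0.23) rose with it. By camera, adjusted p = 1.04e-14, and adjusted p = 0.121 with an estimated correlation. All 22 histidine, tryptophan and arginine genes rose, 22 adjusted over the list alone, trpE by 7.52 ± 0.40 and trpB by 6.96 ± 0.37 (camera adjusted p = 9.46e-19, adjusted p = 0.266 with an estimated correlation). trpD rose from its 1 count by a ratio of 585 (104.7 to 23158), and nadA rose from 2.84 ± 1.69 to 607 ± 93.8 CPM (7.62 ± 0.34, edgeR adjusted p = 1.73e-09). Other CodY targets had 18 of 28 higher (22 adjusted over the list alone), the urease genes ureB (3.54 ± 0.22) and ureA (2.80 ± 0.26) among them; the camera adjusted p = 6.63e-07, and adjusted p = 0.141 with an estimated correlation. Against this, thrC (-3.25 ± 0.20), hom (-2.92 ± 0.19), metN (-3.97 ± 0.26) and metQ (-3.93 ± 0.40) fell; the methionine and cysteine list had 8 of 16 lower and 2 higher (8 and 3 adjusted over the list alone; camera adjusted p = 0.00206, adjusted p = 0.492 with an estimated correlation).

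Ribosomal protein genes had 46 of 52 lower and 1 higher (47 and 1 adjusted over the list alone), with rpmGA (-1.85 ± 0.21), rplV (-1.84 ± 0.20) and rplA (-1.77 ± 0.19), and their share went to 8.42 ± 0.379%. The camera adjusted p = 4.86e-12, and adjusted p = 0.171 with an estimated correlation. Translation factors had 10 of 14 lower, 10 adjusted over the list alone (camera adjusted p = 0.00795, adjusted p = 0.266 with an estimated correlation). All 12 pyrimidine genes fell, also adjusted over the list alone, pyrB (-4.44 ± 0.33) and pyrAA (-4.43 ± 0.39) among them (camera adjusted p = 3.04e-16, adjusted p = 0.263 with an estimated correlation). Purine synthesis did not pass (camera adjusted p = 0.406): 4 genes fell, including purA (-1.53 ± 0.17), 1 rose, and the median (0.06) and mean (-0.22) differed in sign. Purine salvage and uptake did fall, with 7 of 11 lower and 1 higher, the same counts adjusted over the list alone, and a median of -1.13. Its camera adjusted p = 0.00654, adjusted p = 0.266 with an estimated correlation, and the camera adjusted p was 0.0530 with a mean of at least 50 counts. hpf rose (1.01 ± 0.18).

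SigB, oxidative-stress and competence genes and most polyketide genes rose at 16 h. The secretion-stress list fell, and the chaperone list and the SigW and SigM list did not pass. SigB genes had 24 of 34 higher and 2 lower (24 and 2 adjusted over the list alone), with ywzA (5.27 ± 0.35), yflT (3.72 ± 0.28) and gsiB (3.51 ± 0.26). By camera, adjusted p = 2.33e-09, and adjusted p = 0.121 with an estimated correlation. Oxidative stress had 18 of 22 higher (18 adjusted over the list alone), mrgA from 956 ± 373 to 14582 ± 360 CPM (3.93 ± 0.25), msrB by 3.91 ± 0.24, msrA by 3.62 ± 0.23 and ahpF by 3.19 ± 0.20. Its share went from 2.00 ± 0.205% to 8.03 ± 0.10%; the camera adjusted p = 1.71e-09, and adjusted p = 0.198 with an estimated correlation. In ppGpp0 against WT at 8 h this list had 13 higher and 3 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.0379, adjusted p = 0.389 with an estimated correlation), with katA at 2.16 ± 0.18, but the camera adjusted p was 0.0827 with a mean of at least 50 counts. Competence genes had 21 of 23 higher (22 adjusted over the list alone), comGC by 2.92 ± 0.25 (camera adjusted p = 2.43e-08, adjusted p = 0.266 with an estimated correlation); the share ratio was 1.36, and 3.49 with the 20 most abundant genes left out. Polyketide genes had 15 of 24 higher (16 adjusted over the list alone), pksL by 2.73 ± 0.40 (camera adjusted p = 0.00222, adjusted p = 0.413 with an estimated correlation), but their share ratio was 1.2 ± 0.314 and the shares of the libraries overlapped (0.619 and 0.839% at 8 h, 0.778 and 0.966% at 16 h). The secretion-stress list fell, 8 of 11 genes (8 adjusted over the list alone), liaH (-2.56 ± 0.21) among them (camera adjusted p = 0.000690, adjusted p = 0.310 with an estimated correlation). Chaperones and proteases had 8 of 20 lower and 0 higher (camera adjusted p = 0.0575), and SigW and SigM genes had 10 of 21 lower and 3 higher (0.0759); neither list passed, though without ppGpp0 8 h replicate 2 the SigW and SigM list did (camera adjusted p = 0.0376). alsS (4.35 ± 0.22) and alsD (3.50 ± 0.23) rose and ackA (-1.84 ± 0.19) fell. Overflow metabolism, their list, had 5 of 10 higher and 2 lower and did not pass (camera adjusted p = 0.0579).

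**Figure D4:**
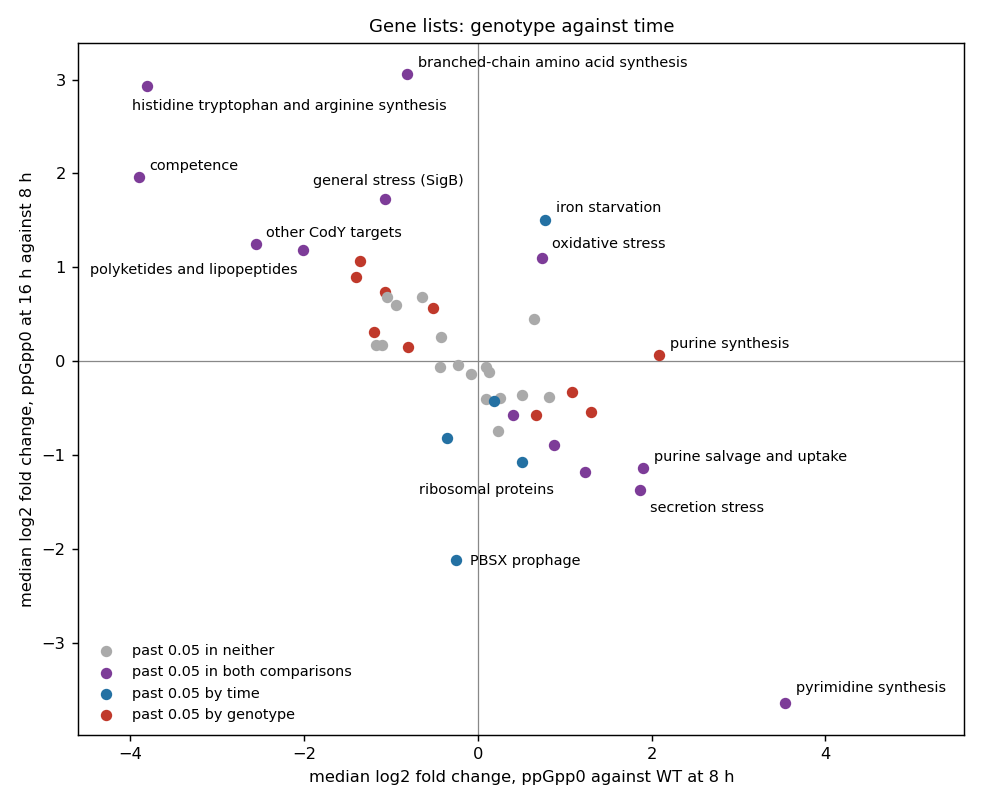
Median log2 fold change of each gene list in ppGpp0 against WT at 8 h (horizontal) and in ppGpp0 at 16 h against 8 h (vertical), coloured by which camera tests passed 0.05. Both axes share the ppGpp0 8 h libraries, which alone pushes lists to opposite sides of 0; oxidative stress passed both tests at the preset correlation with medians above 0 (0.73 and 1.10).

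Many of the same genes changed in both comparisons, in opposite directions. Of 2915 genes without the deleted ones, 1578 changed by genotype, 1392 by time and 993 in both. Among these 435 were lower and then higher, 478 higher and then lower, 22 lower both times and 58 higher both times, where independent lists of these sizes would give 192.7, 184.1, 184.1 and 192.7. The log2 fold changes had r = -0.68 across genes and a covariance of -1.34. Both comparisons share the ppGpp0 8 h libraries, and 20 simulations of unchanged groups, a test chosen after the fold changes were seen, gave r = -0.53, a covariance of -0.0634 and at most 3 genes in both. No gene changed in these simulations, so few could be called. The 3 therefore does not show what overlap to expect where many genes change. In a split also chosen afterwards, with ppGpp0 8 h replicate 1 given to the genotype comparison and replicate 2 to the other, so that no library was in both, the covariance over 2975 genes was -1.36 (r = -0.60), and with the replicates exchanged it was -1.28 (r = -0.56). In these fits each comparison has 1 ppGpp0 8 h library.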

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

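The thinning, the ratio to rRNA and tRNA and both covariance tests were chosen only after the result was seen, as were the bounds set on the shares without the 20 most abundant genes and on the fits without single libraries, which were themselves set before the data were examined.

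The fit that kept non-coding genes, which the report's comparisons leave out, was screened for those with a mean of at least 50 counts. In 4 of them the percent of all counts was higher in both ppGpp0 8 h libraries than in either WT 8 h library. These 4 also passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were the tmRNA gene ssrA (log2 fold change 1.49, adjusted p = 0.0175), the pseudogene ggaA (1.22, adjusted p = 0.00131), the tRNA gene trnSL-Val2 (0.97, adjusted p = 0.00584) and the pseudogene ymfKn (0.59, adjusted p = 0.0481). ggaA, trnSL-Val2 and ymfKn were not weighed further.

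The tmRNA, which frees stalled ribosomes, took 1.13 ± 0.00704% of all counts in WT at 8 h, 2.65 ± 0.962% in ppGpp0 at 8 h and 3.82 ± 1.71% at 16 h. A general rise of small structured RNAs could account for this, and the test planned for it stayed open: the median log2 fold change of the other small RNA genes was -0.77, but it rests on 1 gene, rnpB, which is too few to read as a set. The bound written for that test was unusable for the same reason. A larger carry-over of rRNA and tRNA also stayed open at 8 h, since ssrA counts per rRNA and tRNA count were 0.615 and 3.64 in the ppGpp0 8 h libraries against 0.640 and 0.847 in WT. In the 16 h libraries the ratios were 1.91 and 2.81. There rRNA and tRNA took 1.37 and 1.79% of all counts, against 1.76 and 1.34% in WT at 8 h. These values argue against a larger carry-over in the 16 h libraries alone. Genotype is the biological explanation that the design names at 8 h, and it was not tested apart from the explanations left open.

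Ribosomal protein genes took a larger share of footprints in ppGpp0 at 8 h than in WT. With the 20 most abundant genes left out, the share ratio was 1.84. This argues against abundant genes outside the list setting the shares, and against rpmA, the only member among the 20. It could not test other abundant members, which stayed in. By gene, 47 of 52 members rose. One library driving the difference is argued against by a lowest list median log2 fold change of 1.15 when each of the 4 libraries was left out in turn. After thinning the median was 1.25, but thinning keeps each gene's expected share, so it could not decide on unequal depth. The difference may follow the genotype. The list and its test were fixed before the data were examined, but the thinning and the bounds on the tests above were chosen after the result was seen. A different growth stage of the 2 strains at 8 h was not tested and cannot be told apart from genotype. Camera with an estimated correlation did not call the list (adjusted p = 0.206), and the labels do not describe the replicates as independent.

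Genes that changed in both comparisons mostly changed in opposite directions. The ppGpp0 8 h libraries, shared by both comparisons, push the fold changes apart by chance, but the covariance of -1.34 lies far below the lowest simulated value of -0.0697, which argues against this as the whole cause. With 1 ppGpp0 8 h library given to each comparison, the higher of the 2 covariances was still -1.28, which argues against chance values of single shared libraries. A condition common to both ppGpp0 8 h cultures would remain in this test and may contribute. A later growth stage that WT would also have reached cannot be told apart from a change specific to ppGpp0, because 0 WT libraries at 16 h were analysed.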

How the results depend on the processing

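Keeping row BSU41070 (1593 genes by genotype, 1394 by time) and thinning (1488 and 1297) were chosen after seeing the data; the other alternatives were set before the data were examined. These, with each library left out included, gave 1188 to 1670 changed genes by genotype (1583 in the report) and 963 to 1437 by time (1395), 0 calls reversed direction in any, and the median log2 fold change moved by less than 0.1 in each. Leaving out 1 library gave 450 to 707 genes lower at 16 h (681 in the report), the lowest without ppGpp0 16 h replicate 2; in such fits the lone library is assumed to vary like the other groups. Camera with an estimated correlation called 0 lists by genotype and 0 by time in place of 23 and 18, and fry, which compares no list with other genes, called 32 by time. By genotype the estimate, which rests on 3 residual degrees of freedom, was 0.584 for the histidine, tryptophan and arginine list. For other CodY targets (-0.0148), SigB genes (-0.0234) and translation factors (-0.0393) it lay below the preset 0.01. A higher correlation between genes therefore does not account for the calls lost in these 3 lists. The 2 tests also differed in the simulated 2-fold shift of 1 list by genotype, where genes were drawn independently. The camera adjusted p there was 2.87e-105 at the preset correlation and 0.00447 with an estimated one. A list that misses the second test has thus not been shown to fail through correlated genes. With the 20 most abundant genes left out, share ratios by genotype became 1.5 for translation factors (1.28 in the report) and 0.0818 for competence (0.275). By time they became 7.86 for branched-chain synthesis (9.02), 3.49 for competence (1.36) and 5.02 for oxidative stress (4.01). Each of these lists loses members there. recA leaves competence, tufA and fusA leave translation factors, ilvC leaves branched-chain synthesis, and sodA and ahpC leave oxidative stress. Among 365 gene values, 4 genes changed sign in 5 fits of the 16 h comparison, in which none had passed the threshold, and the cause was not tested: leaving out single libraries, epr ran from -1.02 to 0.013 (without ppGpp0 8 h replicate 2), rsfS from -0.061 (without ppGpp0 16 h replicate 2) to 0.28, bslA from -0.29 to 0.19 (without ppGpp0 8 h replicate 1; 0.05 without ppGpp0 16 h replicate 2), and spoIID from -0.27 (without ppGpp0 8 h replicate 2) to 1.03. Otherwise gene values kept their side of the threshold in 6348 comparisons, lost it in 130 and gained it in 3; 90 list results kept it in 964, lost it in 74 and gained it in 34. With the replicate number as a block, 1618 genes changed by genotype and 1437 by time, and 21 and 18 lists. Same-numbered libraries deviated together with correlations of only 0.057, 0.107 and 0.046. These low values do not show pairing, but counting noise lowers them, so they cannot exclude it. The block lost calls of RNA polymerase and DNA replication lists by genotype (adjusted p = 0.0525 each) and DNA replication by time (0.0596), lost 1 gene value by time, and gained the TCA cycle by time (0.0452). In simulations at this depth, where 139 genes were called by genotype, 12% of 1.5-fold changes were recovered. Far more genes were called in the data (1583), which loosens the adjusted threshold, so that share does not carry over. How many small changes were missed in the data is not known.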

Other observations

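The groups below were fixed with the other lists; naming BSU41070, trpC, trnD-Trp and the pxp genes together here was chosen after their values were seen.

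The unmatched row BSU41070, whose gene is not named here, was the most abundant row by mean count. It took 3.94 ± 0.0160% of all counts in WT at 8 h, 3.34 ± 0.712% in ppGpp0 at 8 h and 4.0 ± 0.0428% at 16 h. Its log2 fold change was 0.03 by genotype (edgeR adjusted p = 0.897) and 0.15 by time (edgeR adjusted p = 0.522). The tryptophan gene trpC, a pseudogene in the annotation used, fell by 6.03 on the log2 scale in ppGpp0 at 8 h and rose by 6.54 at 16 h, while trnD-Trp was 1.73 higher at 16 h than at 8 h (edgeR adjusted p = 0.0204) and had passed no test by genotype (adjusted p = 0.0608).

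Genes of the pxp cluster were among the largest falls from 8 h to 16 h in ppGpp0: pxpR (-5.52 ± 0.33), pxpG (-4.72 ± 0.28) and pxpA (-4.50 ± 0.24). PBSX prophage genes fell there too, 15 of 20 (15 adjusted over the list alone), with xlyA at -3.22 ± 0.49 and xkdF at -3.05 ± 0.34. The list's median was -2.21, or -2.11 with the 2 members at 0 counts set to their bounds (camera adjusted p = 4.0e-05, adjusted p = 0.408 with an estimated correlation). Iron-starvation genes rose, 10 of 17 (11 adjusted over the list alone), with ykuO (3.98 ± 0.44) and the siderophore gene dhbB (3.23 ± 0.36; camera adjusted p = 0.000489, adjusted p = 0.310 with an estimated correlation).

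Motility genes had 17 of 43 lower at 16 h (16 adjusted over the list alone; camera adjusted p = 0.0308, adjusted p = 0.439 with an estimated correlation), motA (-1.41 ± 0.23) among them. The camera adjusted p was 0.0959 without ppGpp0 8 h replicate 1, 0.0664 without ppGpp0 16 h replicate 1 and 0.0519 with a mean of at least 50 counts. In ppGpp0 against WT at 8 h, phosphate-starvation genes had 13 of 17 lower (13 adjusted over the list alone), pstS (-2.20 ± 0.25) among them (camera adjusted p = 0.0121, adjusted p = 0.379 with an estimated correlation). Early sporulation genes had 13 of 19 lower and 2 higher (13 and 2 adjusted over the list alone), spoIIAB (-3.11 ± 0.51) and sigE (-2.06 ± 0.34) among the lower. By camera, adjusted p = 0.0283, and adjusted p = 0.237 with an estimated correlation. The footprint shares of these genes overlapped slightly, with 0.8857 and 0.8435% in WT and 0.8442 and 0.6602% in ppGpp0. Their camera adjusted p was 0.0546 without ppGpp0 8 h replicate 1 and 0.251 with a mean of at least 50 counts.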
